A study of Drosophila mojavensis with 127 samples.

How the data were processed

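Expression was measured in laboratory stocks of the cactophilic fly Drosophila mojavensis, in total RNA labelled with Cy3, on single-colour NimbleGen arrays of the 135K type with 12 arrays to a slide. The labels give population, host cactus, sex and mating status for each of the 127 arrays and do not state the tissue. RNA was purified with a column kit that included DNase digestion and its quality was read on a Bioanalyzer, per the labels' protocols. The series text counts 128 hybridizations, 127 of them in the final analysis, and 15528 transcripts per chip. The table used here holds 127 arrays and 14528 transcript identifiers; the reason for the difference in transcripts is not given in the sources used here.

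The deposited values are log2 expression values made by the authors with RMA (background correction, normalization between arrays and a summary of the probes of a transcript), a tool named without a version per the submitters' processing notes. The log2 scale was inferred from the values, which lay between 4.64 and 15.78. Array medians ran from 10.15 to 10.64, so that the summarised values had not been aligned exactly between arrays, and no centring of transcripts was apparent. The scanner files, slide positions, scan dates and probe-level values were not used here, so that background level, saturation and slide effects could not be examined. For arrays, the number of replicates limits the precision.

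All 14528 identifiers were transcript numbers. The gene table supplied for the species (RefSeq assembly ASM1815372v1, 15130 genes) lists none of them, and 0 identifiers matched, so the files do not pair identifiers with gene names. Lists of genes for egg formation, seminal fluid, sperm and other functions had been fixed before the data were examined; they need gene descriptions and were not run. In their place, transcripts were grouped by their sex difference: male-biased and female-biased transcripts passed the test of sex and differed by more than 2-fold. This grouping was chosen after the values had been seen.

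Titles gave a replicate number within each group of population, host, sex and mating status. Those of replicates 3 and 4 of nonmated San Quintin females on organ pipe add a letter A, which the labels do not explain. In 3 San Quintin groups on organ pipe, 4 pairs of arrays carried the same number; each pair was averaged and counted as 1 replicate, which left 123 replicates, 4 in each of 27 groups and 3 in each of 5 groups. These pairs were not more alike than other arrays of their groups. In San Quintin mated males on organ pipe, for example, the pair correlated at r = 0.940 across transcripts against 0.912 to 0.992 for the other pairs of arrays. No 2 arrays held identical values. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

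One linear model with a mean for each of the 32 groups was fitted to every transcript with limma 3.58.1 (lmFit, contrasts.fit and eBayes with default settings) in R 4.3.3. The model had 91 residual degrees of freedom and a prior worth 4.67. Each comparison was a contrast that weighted its groups equally, and p-values were adjusted by the Benjamini-Hochberg method over all transcripts; a transcript was called at an adjusted p under 0.05. All tests were two-sided. The 16 comparisons, the alternatives and the rule for naming transcripts were set before the data were examined. The tests within single populations and sexes were chosen after the values had been seen; further ones, of other population pairs in each sex, enter only the counts of alternatives. Without gene names, at most 2 identifiers in each direction are given per comparison. For sex, region, host and mating these had the largest differences among called transcripts with one sign of the difference in every stratum of the other factors; for the other comparisons they had the smallest p-values.

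The method was tested on simulated values with the real design, transcript means and spreads, in which 200 of 14528 transcripts were changed. For mating in females it recovered 62% of 50 transcripts changed by 0.25 on the log2 scale, 96% of those changed by 0.5 and 100% of those changed by 1, with 9 calls among unchanged transcripts. For the interaction of region and host it recovered 30%, 80% and 98% at the same sizes. The simulated noise was independent for each transcript, so false calls from variation shared across transcripts were not simulated. On the real arrays with mating labels shuffled, mating in females gave up to 2801 calls.

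Alternatives to the fit were quantile normalization applied again, a shift of each array to the same median, removal of the 25% of transcripts with the lowest mean, separate use of arrays that share a number, the replicate number as a block, a fit to the one sex concerned, array weights, a trended and robust variance prior, and leaving out all arrays of each replicate number in turn. After the data had been seen, 3 more were added: the SD of each array as a covariate, the removal of 2 male arrays whose profile lay nearest the females, and the removal of the Punta Onah arrays. Figures were drawn with matplotlib 3.10.9.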

Results

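The series compared Drosophila mojavensis from 4 localities, reared on fermenting tissue of 2 columnar cacti, to map expression differences due to geography and host plant in both sexes. Punta Onah in Sonora and Organ Pipe National Monument in Arizona lie on the mainland; Punta Prieta and San Quintin lie in Baja California. The host plants were pitaya agria (Stenocereus gummosus) and organ pipe cactus (Stenocereus thurberi). With 2 sexes and mated or nonmated flies this made 32 groups, represented by 127 arrays that counted as 123 replicates, 62 of females and 61 of males. Punta Onah and Organ Pipe National Monument each contributed 32 replicates, Punta Prieta 30 and San Quintin 29. Array medians ranged from 10.15 to 10.64 on the log2 scale, and an array correlated with the others of its group at a mean r of 0.893 to 0.995 across transcripts. The first principal component held 81.4% of the variance among replicates, and sex accounted for 98.7% of the variation along it.

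Sex was by far the largest source of difference. Of the 14528 transcripts, 13523 differed between the sexes, 5368 higher in males and 8155 higher in females. Male-biased transcripts, higher in males by more than 2-fold, numbered 2242, and female-biased transcripts 2928; the remaining 9358 belonged to neither class. The most male-biased transcript, FBtr0172134, averaged 14.19 ± 0.32 (SD, n = 61) in males and 6.30 ± 0.78 (SD, n = 62) in females, a log2 difference of 7.88 ± 0.09 (SE), or 235-fold. FBtr0172595 followed with 7.82 ± 0.10 (SE). The most female-biased transcripts were FBtr0166500, with a male minus female difference of -6.71 ± 0.16 (SE), and FBtr0161796, with -6.62 ± 0.16 (SE); the former averaged 14.64 ± 0.41 (SD, n = 62) in females and 7.96 ± 1.30 (SD, n = 61) in males. The adjusted p-values of these 4 transcripts in limma ranged up to 5.01e-61. The direction was the same in all 16 strata of population, host and mating status for 8425 of the called transcripts.

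A sex index was formed for each array as the mean of the 200 most male-biased minus the mean of the 200 most female-biased transcripts. Female arrays lay between -4.90 and -3.26. Male arrays had a median of 4.74 and a highest value of 5.03. A mated male array from Organ Pipe National Monument on agria (replicate 1) lay between the sexes at 1.06, and a nonmated male array from Punta Prieta on organ pipe (replicate 1) at 2.80. Both were kept in the comparisons.

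**Figure D1:**
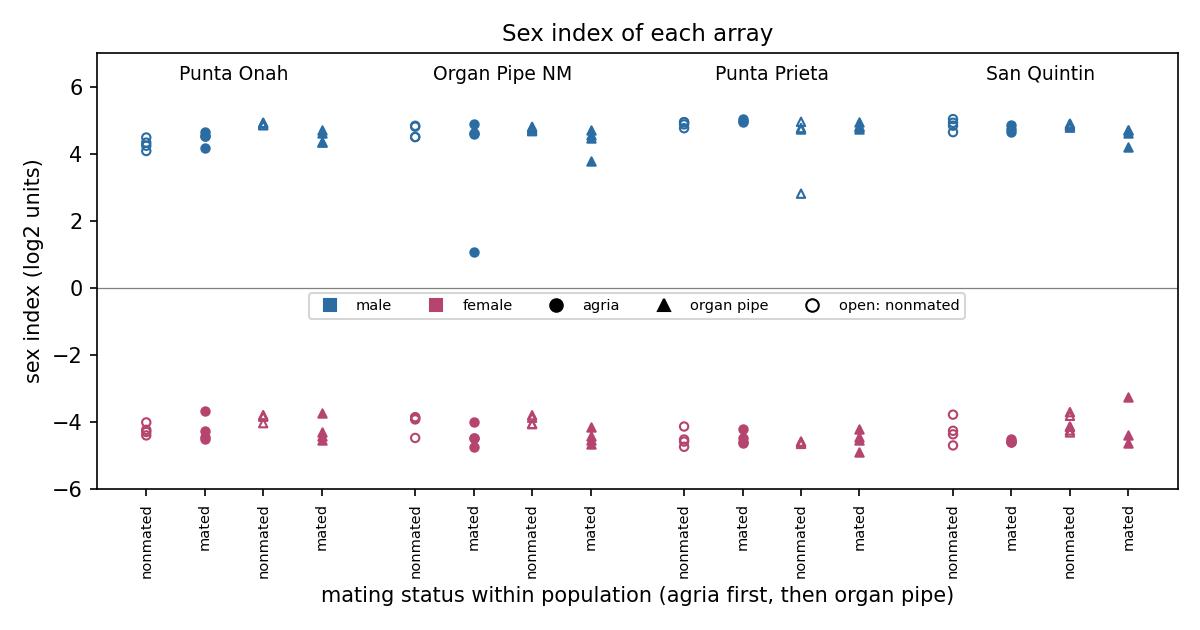
Sex index of each array in log2 units (vertical axis) by population, host and mating status (horizontal axis); each point is an array, blue for males and magenta for females, circles for agria and triangles for organ pipe, open symbols for nonmated flies. Female arrays sit between -4.90 and -3.26, and male arrays sit above them, with 1 mated male array from Organ Pipe National Monument at 1.06.

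The 4 populations differed in 10255 transcripts when both sexes, hosts and mating states were averaged. Without the Punta Onah arrays the other 3 populations differed in 6211. The smallest p-values belonged to FBtr0164933 and FBtr0175546, both far higher in the Baja California populations. FBtr0164933 averaged 5.76 ± 0.34 in Punta Onah (SD, n = 32), 5.51 ± 0.31 in Organ Pipe National Monument (SD, n = 32), 7.82 ± 0.65 in Punta Prieta (SD, n = 30) and 8.05 ± 0.57 in San Quintin (SD, n = 29), with an adjusted p of 3.83e-61. FBtr0175546 averaged 7.95 ± 0.40 and 8.02 ± 0.36 in the mainland populations and 10.56 ± 0.43 and 10.44 ± 0.64 in Punta Prieta and San Quintin (SD; n = 32, 32, 30 and 29), with an adjusted p of 1.51e-55.

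Within the mainland, 6151 transcripts differed between Organ Pipe National Monument and Punta Onah, 2758 higher and 3393 lower in the former. FBtr0175156 was higher in Organ Pipe National Monument by 1.32 ± 0.05 (SE, log2) and FBtr0168369 by 1.66 ± 0.08 (SE). FBtr0172428 had a difference of -2.39 ± 0.14 (SE), from 12.86 ± 0.76 in Punta Onah to 10.47 ± 0.58 in Organ Pipe National Monument (SD, n = 32 each), and FBtr0167957 one of -0.84 ± 0.05 (SE). In males the 2 populations differed in 8450 transcripts and in females in 697, and the difference itself varied with sex in 6729 transcripts. Within Baja California, San Quintin and Punta Prieta differed in 1718 transcripts, 861 higher and 857 lower in San Quintin, and only 2 of them by 2-fold or more. FBtr0161183 was higher in San Quintin by 0.76 ± 0.10 (SE) and FBtr0168074 by 0.31 ± 0.04 (SE), while FBtr0161522 had a difference of -0.94 ± 0.12 (SE) and FBtr0171481 one of -0.26 ± 0.03 (SE). The adjusted p-values of these 8 transcripts in limma were at most 2.85e-07. After a shift of all arrays to the same median, 57.9% instead of 44.8% of the calls between the mainland populations were higher in Organ Pipe National Monument, and 60.4% instead of 45.8% of those in females. The count for San Quintin was 231 without replicate 2, 764 without replicate 3 and 3952 with array weights, the mainland count 4099 without replicate 3, and the female count of 697 lay between 230 and 439 without each replicate number and at 3578 with array weights.

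Region, the contrast of Baja California with the mainland, was tested in each sex. In females 3755 transcripts differed, 1519 higher and 2236 lower in Baja California, of which 18 were higher and 22 lower by at least 2-fold. In males 6711 differed, 2818 higher and 3893 lower, of which 45 were higher and 33 lower by at least 2-fold. In females FBtr0164933 rose by 2.92 ± 0.07 (SE, log2; 7.55-fold), from 5.55 ± 0.28 on the mainland (SD, n = 32) to 8.46 ± 0.29 in Baja California (SD, n = 30); the mainland level is near the lowest values on the arrays (4.64 to 5.30), so that this fold is at best a lower bound. FBtr0167831 rose by 2.28 ± 0.12 (SE). FBtr0162622 fell by 2.50 ± 0.24 (SE) and FBtr0172679 by 1.86 ± 0.08 (SE). In males FBtr0175546 rose by 3.03 ± 0.09 (SE; 8.17-fold) and FBtr0175386 by 2.17 ± 0.10 (SE), whereas FBtr0172679 fell by 2.23 ± 0.09 (SE) and FBtr0172275 by 1.63 ± 0.12 (SE). The largest adjusted p-value among them in limma was 5.74e-15.

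The region differences of the sexes were correlated across transcripts (r = 0.464; transcripts are not independent replicates). Of the 2194 transcripts called in both sexes, 1917 had the same direction, 616 higher and 1301 lower in Baja California in both sexes, against 295 and 599 for independent lists. Each region rests on 2 populations, so that differences between regions cannot be separated from differences between these populations, and in males the pairing of Organ Pipe National Monument with San Quintin gave 7053 calls. The female count was 2456 without replicate 2, 2216 without replicate 3, 6806 with array weights and 2016 without Punta Onah; the transcripts higher by at least 2-fold numbered 9 without the dimmest transcripts and 29 with array weights in females, and 72 with the array SD as a covariate in males, and after a shift to the same median 49.8% instead of 42.0% of the male calls were higher in Baja California.

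Sex-biased transcripts moved in opposite ways in the 2 sexes. In Baja California males 960 male-biased transcripts were higher and 95 lower than in mainland males, and 284 female-biased transcripts were higher and 956 lower. In Baja California females 532 female-biased transcripts were higher and 171 lower, and 140 male-biased transcripts were higher and 373 lower, the last majority shrinking to 240 against 287 after quantile normalization. The interaction of sex and region passed the test in 3507 transcripts: 749 male-biased transcripts had a more positive region difference in males than in females and 28 a less positive one, against 78 and 765 of the female-biased transcripts. The sex difference was therefore wider in the Baja California than in the mainland populations for most of the sex-biased transcripts called. Between the 2 mainland populations it varied in more transcripts, 6729, so this cannot be taken as a trait of the region. The count for sex by region was 888 without Punta Onah and 5261 with the array SD as a covariate. The majorities in the interaction had the same direction under both other scalings and without the 2 male arrays nearest the females, where the interaction counts were 682 and 37 for male-biased and 118 and 761 for female-biased transcripts. The shifts were small, with a median interaction of 0.22 (log2) over male-biased and -0.13 over female-biased transcripts. FBtr0175386 and FBtr0172763 had the most positive interactions by p, 2.01 ± 0.14 and 1.56 ± 0.11 (SE). FBtr0174094 and FBtr0164933 had the most negative, -1.99 ± 0.15 and -1.23 ± 0.10 (SE). All 4 adjusted p-values in limma were at most 6.7e-18. The mainland level of FBtr0164933 lay near the lowest values on the arrays, so the size of its interaction is uncertain.

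**Figure D2:**
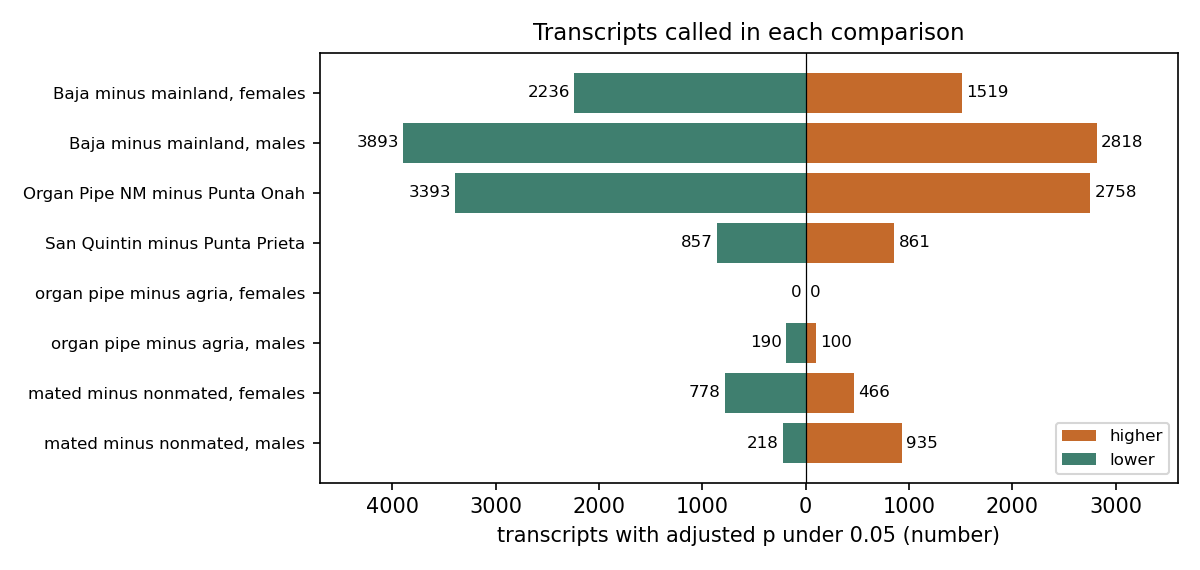
Number of transcripts called at an adjusted p under 0.05 (horizontal axis), higher to the right and lower to the left, for 8 comparisons (vertical axis). Region differences, with 3755 calls in females and 6711 in males, outnumber mating differences, with 1244 and 1153, and host differences, with 0 and 290.

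Few transcripts differed between host cacti when the 4 populations were averaged. In females limma called 0 transcripts between organ pipe and agria (smallest adjusted p 0.108), and 1301 had an unadjusted p under 0.05. In males 290 transcripts were called, 100 higher and 190 lower on organ pipe, none by 2-fold. FBtr0172993 rose on organ pipe by 0.41 ± 0.08 (SE, log2; adjusted p = 0.000993), and FBtr0171672 by 0.21 ± 0.05 (SE; adjusted p = 0.00817). FBtr0165270 fell by 0.53 ± 0.12 (SE; adjusted p = 0.00567) and FBtr0166509 by 0.44 ± 0.10 (SE; adjusted p = 0.00343). The same direction in all 8 strata of population and mating status held for 19 of the 290. Host differences in males and females were negatively correlated across transcripts (r = -0.228). The interaction of sex and host passed the test in 193 transcripts, 41 with a more positive host difference in males and 152 with a more negative one; FBtr0165842 had an interaction of -0.75 ± 0.10 and FBtr0172678 one of -0.77 ± 0.11 (SE), and FBtr0167575 and FBtr0165806 had 0.63 ± 0.13 and 0.39 ± 0.08 (SE). The male count ranged from 30 to 265 without each replicate number and was 56 without the dimmest transcripts, 121 in a fit to males alone, 1732 with array weights, 952 with the SD of each array as a covariate and 33 without Punta Onah; array weights gave 2502 calls in females, and the interaction count was 55 after quantile normalization, 33 to 186 without each replicate number and 4 without Punta Onah. The share of male calls higher on organ pipe was 34.5%, against 48.2% after quantile normalization and 25.1% after a shift to the same median, and none of the 4 named transcripts stayed called in every alternative.

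Within single populations more transcripts differed between hosts in some cases, and the host difference varied among populations. In Punta Onah males 5363 transcripts differed between hosts, 2430 higher and 2933 lower on organ pipe. Organ Pipe National Monument males had 1756, San Quintin males 706 and Punta Prieta males 0 such transcripts, the last with 384 at an unadjusted p under 0.05. Among females, Punta Onah had 542, San Quintin 677, Punta Prieta 2 and Organ Pipe National Monument 1. A test of whether the host difference varied among populations called 6455 transcripts in males (4228 without replicate 1 and 2959 without replicate 3) and 1263 in females (555, 17 and 542 without replicates 1, 3 and 4, and 5651 with array weights). The host differences of the 4 populations had a mean pairwise correlation across transcripts of -0.165 in males and -0.141 in females, and the highest pair, Punta Onah and San Quintin females, reached 0.633. In Punta Onah males the count stayed between 3590 and 4635 without each replicate number, whereas it fell as low as 60 in Organ Pipe National Monument males (without replicate 3), 4 in San Quintin males (without replicate 1), and 0 in Punta Onah females (without replicate 4) and San Quintin females (without replicate 3); the 2 calls in Punta Prieta females were 0 after quantile normalization, without the dimmest transcripts and without replicate 1, 2 or 4, and array weights gave 2276 in Punta Prieta males, 763 in Punta Prieta females, 1637 in Organ Pipe National Monument females, 4689 in Punta Onah females and 2457 in San Quintin females. Quantile normalization turned the majority in Punta Onah males, from 45.3% to 52.6% higher on organ pipe, and in San Quintin males, from 49.4% to 53.4%, and a shift to the same median changed the share of calls higher on organ pipe from 25.5% to 45.1% in Punta Onah females, from 5.02% to 16.4% in San Quintin females and from 49.4% to 33.8% in San Quintin males.

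**Figure D3:**
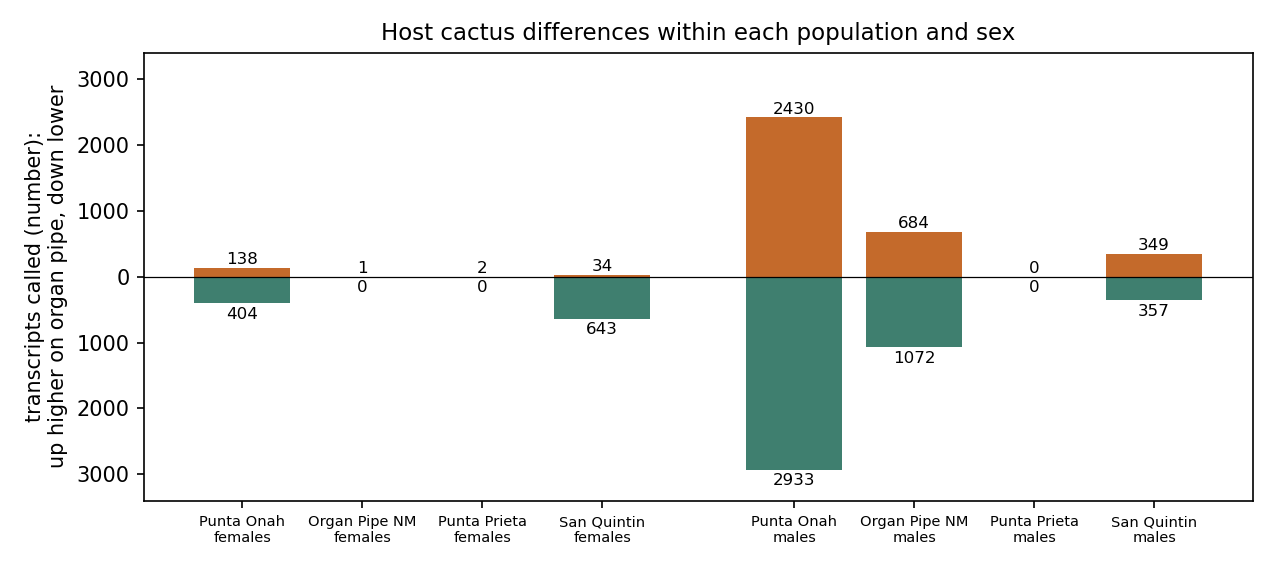
Number of transcripts that differed between organ pipe and agria (vertical axis; bars upward for higher on organ pipe, downward for lower) in each population and sex (horizontal axis). Punta Onah males have 2430 and 2933 calls, and Punta Prieta males none.

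Mating changed a small set of transcripts strongly in females. Of 1244 transcripts called between mated and nonmated females, 466 were higher and 778 lower in mated females, and 56 were higher by at least 2-fold against 4 lower by as much. Of the 56, 52 belonged to the female-biased class, where 11.3 would fall if list and class were independent, and 3 to the male-biased class. They are not fully independent: the class was set from all flies, so a rise in mated females itself adds to the female bias. FBtr0165289 rose by 2.32 ± 0.16 (SE, log2; 4.99-fold), from 10.09 ± 1.23 in nonmated (SD, n = 31) to 12.41 ± 0.63 in mated females (SD, n = 31), and FBtr0163647 rose by 2.19 ± 0.18 (SE). FBtr0167250 fell by 1.24 ± 0.09 (SE; 2.36-fold) and FBtr0163377 by 1.23 ± 0.09 (SE). Over all 56 transcripts the mean log2 value was 12.58 ± 0.41 (SD, n = 31) in mated and 11.22 ± 0.72 (SD, n = 31) in nonmated females, a difference that follows from how these transcripts were chosen; over the 8 strata of population and host it ranged from 0.70 to 2.27. Over all 2928 female-biased transcripts the median difference was -0.01. The number higher by at least 2-fold stayed between 50 and 62 in all alternatives, 50 of them shared without Punta Onah. The full count was 598 without replicate 3 and 4224 with array weights, and shuffled mating labels gave up to 2801 calls.

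In males 1153 transcripts differed with mating, 935 higher and 218 lower in mated males, and 10 were higher by at least 2-fold, of which 6 were male-biased and 2 female-biased (7 to 15 higher without each replicate number and 17 with array weights). FBtr0175092 rose by 1.64 ± 0.08 (SE, log2; 3.11-fold), from 11.20 ± 0.60 (SD, n = 32) to 12.79 ± 0.50 (SD, n = 29), and FBtr0174096 by 1.16 ± 0.10 (SE). FBtr0175171 fell by 0.94 ± 0.10 (SE) and FBtr0168663 by 0.86 ± 0.13 (SE). The adjusted p-values of the 8 transcripts named for mating in either sex were at most 5.75e-07 in limma. The share higher in mated males was 81.1%, against 71.7% after quantile normalization and 58.2% after a shift to the same median. The count lay between 621 and 915 without each replicate number (630 without replicate 2 and 621 without replicate 3) and was 3426 with array weights.

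Mating was also compared within single populations. In females of Organ Pipe National Monument 475 transcripts were higher and 1299 lower in mated flies, whereas 130 were higher and 54 lower in Punta Onah, 42 and 9 in Punta Prieta, and 297 and 40 in San Quintin. In males 625 were higher and 360 lower in Punta Onah, 411 and 85 in Organ Pipe National Monument, 152 and 13 in Punta Prieta, and 367 and 26 in San Quintin. On organ pipe, mated Punta Onah males were among the first 12 arrays by title number, as many as a slide holds, and nonmated ones were not. The labels do not say which arrays shared a slide, so an effect of slide cannot be told apart from mating there. The share higher went from 26.8% to 59.0% in Organ Pipe National Monument females after a shift to the same median, from 63.5% to 31.9% in Punta Onah males, from 82.9% to 66.2% in Organ Pipe National Monument males and from 88.1% to 65.8% in San Quintin females, and from 93.4% to 81.0% in San Quintin males after quantile normalization. Without each replicate number the counts ranged from 475 to 1860 in Organ Pipe National Monument, 76 to 255 in Punta Onah, 22 to 33 in Punta Prieta and 122 to 414 in San Quintin females, and from 85 to 1090, 332 to 787, 52 to 263 and 103 to 308 in the males of these populations. Of 100 splits of the mating labels, the real one included and the others shuffled, 9 reached the count of Organ Pipe National Monument males and 6 that of San Quintin males (393). The count of Organ Pipe National Monument males was 496, with 192 without the 2 male arrays nearest the females and 248 with array weights. Array weights raised the counts to 5183 in Organ Pipe National Monument, 1056 in Punta Onah, 764 in Punta Prieta and 2658 in San Quintin females. In males they gave 1768 in Punta Onah and 4675 in Punta Prieta.

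The mating differences of the sexes showed little relation across transcripts (Pearson r = -0.002, Spearman rho = -0.162; transcripts are not independent replicates). Of the 153 transcripts called in both sexes, 129 had the same direction, 77 higher and 52 lower, against 30.0 and 11.7 for independent lists. FBtr0167250 and FBtr0163377, the most reduced in mated females, were also lower in mated males, with differences of -0.82 and -0.85 (log2). The interaction of sex and mating passed the test in 1114 transcripts, among them 55 of the 56 transcripts raised at least 2-fold in mated females. FBtr0175092 and FBtr0164125 had a more positive mating difference in males, 2.82-fold and 1.64-fold, and FBtr0162044 and FBtr0165289 a more negative one, by -1.61 ± 0.16 and -2.27 ± 0.22 (SE, log2). The interaction count was 405 to 735 without each replicate number and 4813 with array weights. More positive differences in males made up 63.6% of it, against 42.3% after a shift to the same median.

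**Figure D4:**
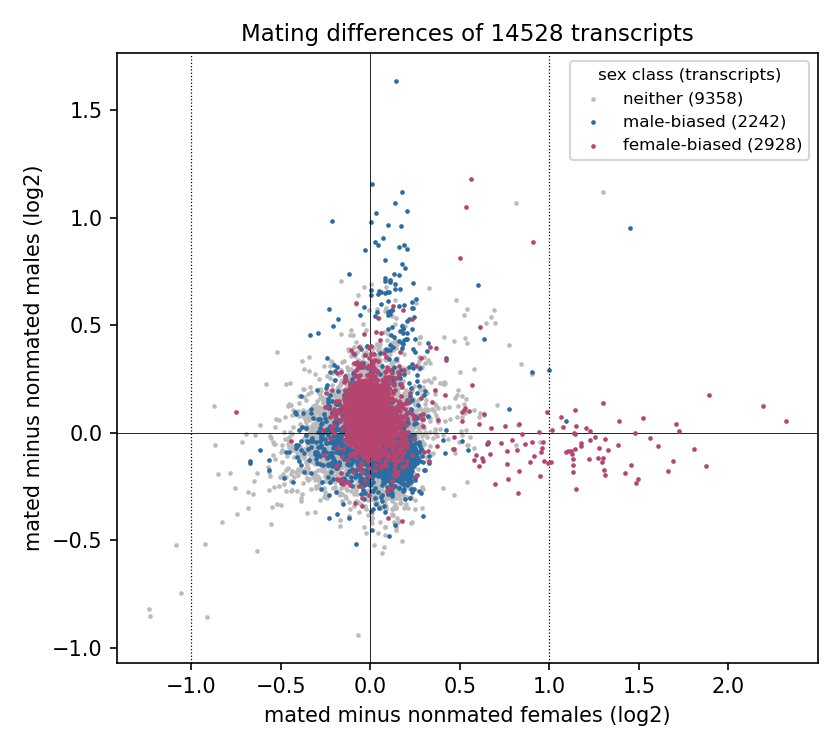
Log2 difference between mated and nonmated females (horizontal axis) and males (vertical axis) for each of 14528 transcripts, coloured by sex class; dotted lines mark a 2-fold difference in females. Female-biased transcripts form an arm to the right, where 52 of the 56 transcripts called at or beyond the right dotted line belong to that class.

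The mating and host differences were also set against region with both sexes averaged. The interaction of region and mating passed the test in 1849 transcripts. Of these, 439 female-biased transcripts had a more negative mating difference in Baja California and 11 a more positive one, whereas 125 male-biased transcripts had a more positive and 11 a more negative one. The 2 male arrays nearest the females, a mated mainland and a nonmated Baja California male, add to both majorities. Without them the counts were 305 and 20 for female-biased and 96 and 28 for male-biased transcripts. The median interaction was then -0.08 instead of -0.12 (log2) over female-biased and 0.04 instead of 0.08 over male-biased transcripts. By p, the most positive interactions were those of FBtr0168550 and FBtr0163151, 0.46 ± 0.07 and 0.41 ± 0.07 (SE, log2), and the most negative those of FBtr0162701 and FBtr0162016, -0.38 ± 0.07 and -0.37 ± 0.07 (SE). The interaction of region and host passed the test in 650 transcripts, 490 with a more positive organ pipe minus agria difference in Baja California. FBtr0165351 and FBtr0165626 had interactions of 0.73 ± 0.12 and 0.71 ± 0.13 (SE), and FBtr0168369 and FBtr0168346 of -0.87 ± 0.12 and -0.77 ± 0.14 (SE). The interaction of host and mating gave 0 calls in limma (smallest adjusted p 0.205), with 2402 transcripts at an unadjusted p under 0.05, and 33 calls with array weights.

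Single replicate numbers decided much of these interaction counts. The region by mating count was 12 without replicate 1, 511 without replicate 2, 531 without replicate 3 and 2539 at most. The region by host count was 126, 77, 4 and 397 without replicates 1 to 4, 2556 with array weights, 3696 with the array SD as a covariate and 1476 without Punta Onah, and its share of positive interactions was 75.4%, against 51.8% after quantile normalization and 33.8% after a shift to the same median.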

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

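The tests of a female sample under a male label, of mixed RNA and of female RNA in Punta Onah males (its bounds before the value), and the comparisons within single populations, were chosen only after the results were seen, and the bounds for shuffled labels in this part were written down after most of the shuffles had been run.

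Of 81 tests for a sample far from the others of its group (27 groups of 4 and 3 measures), 4 passed the critical ratio of Dixon's test, where chance gives 4.05. The sex index was 1.06 in replicate 1 of mated Organ Pipe National Monument males on agria, against at most 4.88 in the others. It was 2.80 in replicate 1 of nonmated Punta Prieta males on organ pipe, against 4.72 to 4.95. In replicate 4 of nonmated Organ Pipe National Monument females on agria it was -4.48, against -3.93 to -3.86. The array median was 10.58 in replicate 4 of nonmated San Quintin females on agria, against 10.48 to 10.49.

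The male array at 1.06 was weighed against 3 technical explanations. A female sample under a male label is argued against by the index itself, which lay far above the highest female value of -3.26 (SD among females 0.34). A compressed signal range is argued against by the slope of this array on its group over transcripts of neither sex class, 1.04, with 0.966 to 1.01 for the others of the group. A mixture of male and female RNA may remain, but the share of female RNA was 38.2% from female-biased and 60.3% from male-biased transcripts, a difference of -0.221 that lies between the bounds set for and against it, whereas the 200 most biased transcripts of each class gave 46.2% and 46.0%, as a mixture would. The estimate depends on the transcripts used, so the mixture stays open, and no biological explanation was tested.

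The Organ Pipe National Monument against Punta Onah difference varied with sex in 6729 transcripts (highest count 1535 in the other 99 shuffles), and the host difference was widest in Punta Onah males. The median sex index was lower in Punta Onah males on agria (4.40) than in those on organ pipe (4.78), but female RNA as the whole cause is argued against by the 66.6% (populations in males) and 71.5% (host in Punta Onah males) of called transcripts that lay in neither sex class and differed by more than the 0.14 that female RNA at a share of 10% could make there; a computed mixture at that share had a sex index of 3.23, below the lowest Punta Onah male (4.08). Variation shared between replicate arrays, of whatever origin, could account for part of both: of the squared difference, 38.9% for the populations in males and 26.1% for the host in Punta Onah males lay along the first 5 axes of replicate variation in the other groups, values between the bounds set for and against it. The share was also 35.0% for the populations in females, so the measure does not account for the contrast between the sexes. It was 62.3% for host in Punta Onah females, 63.8% for host in San Quintin males and 4.54% for region in males. Sex involves every group, so its share, 75.1%, had no other groups to draw axes from. The groups used include the male arrays at a sex index of 1.06 and 2.80, which lie toward the females within their groups. The share for sex therefore cannot show whether a high share marks replicate variation. The groups left out differ between comparisons, so the shares have no common basis. Differences between stocks, a response to the host and an effect of slide or array order stay open, untested. By title number the first 12 arrays, as many as a slide holds, were Punta Onah males on agria and mated ones on organ pipe. They lay at 10.8 to 53.2 on the third principal component, against -19.3 to -5.3 for nonmated Punta Onah males on organ pipe. The labels do not say which arrays shared a slide.

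The remaining differences between groups are counts of transcripts that passed the test of an interaction, each set against 100 splits, the real one included, with the labels shuffled among arrays that share the other factors. Before these shuffles the average host, mating or population difference of each transcript was taken off, which leaves the real interaction as it was. The same was done above for the shuffles of the mainland difference by sex. Sex by region had 3507 transcripts (highest other split 163), sex by host 193 (60), sex by mating 1114 (2), region by host 650 (25) and region by mating 1849 (1621); in each of these only 1 of the 100 splits, the real one, gave as many. Host differences varied among populations in 1263 transcripts in females (368) and 6455 in males (3419), again reached by 1 split of 100. Mating differences varied among populations in 808 transcripts in females, reached by 2 splits of 100 (highest other 828); the count was 294, 141 and 318 without replicates 1, 2 and 3, 474 with same-numbered arrays separate, 1270 after a shift to the same median and 4590 with array weights. In males the number was 287, reached by 7 splits of 100 (highest other 1766), so that chance is not excluded, and it was 32, 63, 113 and 997 without replicates 1 to 4, 2169 with array weights and 973 with the array SD as a covariate. Host by mating gave 0 calls in limma with 2402 transcripts at an unadjusted p under 0.05, so that the splits (highest other 13), all 100 of which reach 0, say nothing about chance.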

How the results depend on the processing

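The alternatives with the SD of each array as a covariate, without Punta Onah and without 2 male arrays were chosen after the data had been seen. Of the 16 counts of calls, 14 stayed within 1.5 times under quantile normalization applied again, which gave 55 for sex by host and 411 for region by host, and all 16 did so after a shift to the same median and with a trended, robust prior. A similar count need not hold the same transcripts. After the shift region by host had 669 calls, among them 386 of the 650 of the main fit, whereas 13245 of 13523 calls were shared for sex. Without the dimmest transcripts host in males gave 56 and sex by host 26. With same-numbered arrays kept separate sex by host gave 128 and region by host 406, and a fit to males alone gave 121 for host in males. Array weights moved 10 counts: region in females 6806, San Quintin against Punta Prieta 3952, host in females 2502, host in males 1732, mating in females 4224, mating in males 3426, sex by host 2523, sex by mating 4813, region by host 2556 and host by mating 33. With the array SD as a covariate host in females gave 4, host in males 952, mating in males 1868, sex by region 5261, sex by host 1601 and region by host 3696. Without Punta Onah the count was 6211 for population, 2016 for region in females, 3 and 33 for host in females and males, 618 and 512 for mating in females and males, 888 for sex by region, 4 for sex by host, 383 for sex by mating and 1476 for region by host; with fewer arrays and populations these contrasts also average over other groups. Without each replicate number in turn, region in females ranged from 2216 to 2988, Organ Pipe National Monument against Punta Onah from 4099 to 5678, San Quintin against Punta Prieta from 231 to 1618, host in females from 0 to 15, host in males from 30 to 265, mating in females from 598 to 1090, mating in males from 621 to 915, sex by host from 33 to 186, sex by mating from 405 to 735, region by host from 4 to 397 and region by mating from 12 to 2539. Leaving out a number leaves fewer arrays; beyond that the cause was not tested for any of these changes. Without the 2 male arrays nearest the females none of the 16 counts moved by over 1.5 times, whereas host in Punta Prieta females went from 2 to 16 and mating in Organ Pipe National Monument males from 496 to 192. For the 52 named results, 706 of 730 alternative values kept direction and call, 24 kept the direction and lost the call, and 0 reversed. Of 515 alternative counts for the comparisons within sexes or populations and the 2-fold counts, 379 stayed within 1.5 times and 136 did not.

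Replicate numbers did not pair the samples: deviations from group means correlated at a mean r of -0.002 between groups for equal numbers and 0.001 for unequal numbers, and 38 of 123 replicates correlated best with their own number. With the number as a block the counts were close to those without it, for example 1244 and 1253 for mating in females, and no count of the 16 moved by over 1.5 times. Gene list tests with an estimated correlation were not run, since the lists need gene descriptions. Signal over background was not used here, so that differences of dim transcripts have no separate check.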

Other observations

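The test of neighbouring identifiers, the use of shuffled mating labels against shared replicate variation, the median over all female-biased transcripts, the pairings of the populations and the comparisons within populations were chosen only after the results were seen, and the bounds for shuffled labels were written down after most shuffles had been run, except those for differences of at least 2-fold.

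Over the 56 transcripts at least 2-fold higher in mated females, the mean in nonmated Punta Prieta females was 12.21 on agria and 11.98 on organ pipe, against 10.60 to 11.49 in the nonmated females of the other populations. The rise with mating was 0.70 and 0.76 in Punta Prieta (agria and organ pipe), 1.38 and 1.71 in Punta Onah, 0.999 and 1.498 in Organ Pipe National Monument, and 1.48 and 2.27 in San Quintin. Of the 56, 14 passed the test that the mating difference varied among populations in females. In males the mean was 8.66 ± 0.42 in mated (SD, n = 29) and 8.66 ± 0.42 in nonmated flies (SD, n = 32), and 3 of the 56 were called higher in mated males.

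That 52 of these 56 transcripts were female-biased (11.3 if list and class were independent, which they are not fully) was weighed against 2 technical explanations. A larger share of all female-biased tissue in mated females is argued against by the median difference of all female-biased transcripts, -0.00755 (quartiles -0.05 and 0.04). Variation shared between replicate arrays, which stays in the arrays when mating labels are shuffled, is argued against by the shuffles: no other split called more than 1 transcript with at least a 2-fold difference, against 60 (56 higher and 4 lower) with the real labels. A technical difference that follows mating status in every group stays open, since slides and dates were not used here. A response of a restricted set of female transcripts to mating also stays open.

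Transcripts of this set may be co-regulated as neighbouring models, if identifier numbers follow position, which was not tested. Of the 56 members, 18 had another member within 5 identifier numbers, against a median of 2 and a highest value of 12 in 10000 random lists of female-biased transcripts (permutation p = 0.0001, the smallest these lists can give). Duplicated or overlapping probe sets of neighbouring models would give the same pattern and were not tested.

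Labels were also shuffled 99 times, among arrays that share the other factors, for the other comparisons, and the number of splits, the real one included, that gave a result as large is out of 100. It was 1 for sex (13523 transcripts, highest other 6596), population (10255, 30), region in females (3755, 1), region in males (6711, 2200), Organ Pipe National Monument against Punta Onah (6151, 1645), San Quintin against Punta Prieta (1718, 0), and Organ Pipe National Monument against Punta Onah in females (697, 0) and in males (8450, 4493). A chance assignment of single arrays is thus excluded at 0.05 for these. For region such shuffles show only that populations differ, since they cannot separate the geographic pairing from other pairings. With 3 ways to pair the 4 populations, a share under 0.05 cannot be reached: the geographic pairing called 3755 transcripts in females (1 of 3 ways as large, highest other 573) and 6711 in males (2 of 3, highest other 7053).

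For host in males 6 splits reached the 290 calls (highest other 2798), so that chance is not excluded. The 0 calls in females (highest other 1505) and in Punta Prieta males (highest other 1) are reached by all 100 splits by construction, which says nothing about chance. Within populations the tests were taken singly, with no correction for their number. A share of splits under 0.05 reached the count in Punta Onah females (1 split, 542, highest other 8) and males (1 split, 5363, 4615). The same held in Organ Pipe National Monument males (4 splits, 1756, 3858) and Punta Prieta females (4 splits, 2, 53), where the 2 calls were 0 without replicate 1, 2 or 4. It also held in San Quintin females (1 split, 677, 360) and males (3 splits, 706, 1700). Where 3 or 4 splits reached the count, another split gave more calls, so chance is not firmly excluded there. The San Quintin female count was 0 without replicate 3. Replicates 3 and 4 of nonmated San Quintin females on organ pipe lay at -50.4 and -45.3 on the fourth principal component, against -4.2 and -9.9 for replicates 1 and 2. Chance was not excluded in Organ Pipe National Monument females (17 splits, 1, 1508). The negative mean correlation between populations of the host difference was reached by 2 splits in males (-0.165, most negative other -0.195) and by 6 in females (-0.141, -0.198), where chance is not excluded.

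For mating, 3 splits reached the 1244 calls in females (highest other 2801), so that chance is not firmly excluded for that count. In males 1 split reached the 1153 calls (highest other 659). Within populations the tests were again taken singly, with no correction for their number. A share of splits under 0.05 reached the count in females of Punta Onah (1 split, 184 calls, highest other 1), Organ Pipe National Monument (1 split, 1774, 801), Punta Prieta (3 splits, 51, 1993) and San Quintin (2 splits, 337, 391). The same held in males of Punta Onah (2 splits, 985, 1322) and Punta Prieta (1 split, 165, 145). Where 2 or 3 splits reached the count, another split gave more calls, so chance is not firmly excluded there. Chance is not excluded in males of Organ Pipe National Monument (9 splits, 496, 2409) or San Quintin (6 splits, 393, 3142). The counts with at least a 2-fold difference, 60 in females (highest other 1) and 10 in males (highest other 0), were reached by 1 split each. The mean correlation between populations of the mating difference was 0.332 in females, reached by 6 splits (highest other 0.653), and 0.144 in males, reached by 12 (highest other 0.371), so that chance is not excluded for either. Some splits gave several times the real count, such as 2798 against 290 for host in males. Structure among the replicate arrays that the labels do not name could give this. So could real host differences within populations, which stay in the shuffled arrays, and these were not told apart.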
